A study of Mus musculus with 6 samples.

How the data were processed

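RNA from flow-sorted splenic CD11c-positive dendritic cells of C57Bl/6 mice was measured on Affymetrix 3' expression arrays, 1 array per sample, with 3 wild-type samples and 3 Map3k7-knockout samples. Per the labels' protocols, both groups received tamoxifen in vivo for 3 days, and biotin-labelled cRNA was made from 100 ng of RNA per sample. Deletion, the Cre transgene and any response to deletion elsewhere in the mouse come together in the knockout group and were not separated. The labels name no batch, slide or scan date.

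The deposited values are on a log2 scale and were made by the authors with RMA, which corrects background, normalizes arrays by quantiles and summarises the probes of each probe set, in Affymetrix Expression Console 1.1, per the submitters' processing notes. That scale was read from the values, which lie between 2.58 and 13.9. Array medians were 3.77 to 3.81, and no pair of arrays held identical values (0 pairs). RMA leaves no count or detection call, and a transcript near the array median may be unexpressed, so folds of dim genes are understated. Arrays give no depth, and their number limits the precision.

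The table held 45141 probe sets, of which 104 were Affymetrix controls and 45037 were tested. The platform annotation gave 28898 of these 1 gene symbol, 551 several symbols and 15588 none. Through the Entrez gene ID 28689 probe sets were matched to the RefSeq gene table, which changed 0 symbols. No gene was named from a probe set with several symbols. Each of 17097 genes was represented by its probe set with the highest mean over the 6 arrays. Of the 285 genes past the threshold, 144 had more than 1 probe set, 114 of these had all probe sets in one direction, and 0 had a probe set past the threshold in the other direction. Coordinates are not given, since the sources used here name no genome build.

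Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings, no covariates) as knockout minus wild type, with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. Gene lists were tested with camera (limma, 2-sided, preset inter-gene correlation 0.01) on the representative probe sets, with Benjamini-Hochberg adjustment over 22 pathway lists and, separately, over 15 cell type lists. The lists, the tests, the rule for named genes and the alternatives, except those named below, were chosen before the data were examined. The rule took Map3k7, the 12 largest positive and 12 largest negative differences among genes past the threshold whose groups did not overlap, unnamed clones passed over, and from each list up to 4 members past the threshold or, with fewer than 2, the 2 members with the smallest p. Genes named only in the closing part on other observations lie outside this rule.

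The alternatives were the probe sets at or above the median level, no probe sets ending in x or s (which can match several transcripts), further centring or quantile normalization, the mean or the smallest-p probe set of a gene, trended and robust variances, array weights, the replicate number as a block, other thresholds, camera with an estimated correlation, fry, and leaving out each array in turn. Lists without shared genes, and counts without macrophage, monocyte and neutrophil markers, were added after seeing the data. Single values were compared by 2-sided exact permutation, for which 3 against 3 arrays cannot go below p = 0.1. On simulated data with known differences the limma step over 45037 probe sets recovered 4% of changes of 0.5 on the log2 scale, 48% of changes of 1, 96% of changes of 2 and 100% of changes of 3, with 7 false calls among 131. Camera called the shifted list and 0 of 20 unshifted lists in that test. Its genes were simulated as independent, so it does not show how often the preset correlation gives false calls among correlated genes. The limma changes were placed only in probe sets at or above the median level, and variances were shuffled over all probe sets. The recovery shares therefore do not cover dim genes and may differ from those in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.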

Results

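Gene expression was measured in CD11c-positive dendritic cells, the antigen-presenting cells of the spleen, sorted by flow cytometry from C57Bl/6 mice. Wild-type mice and mice carrying an inducible Cre for deletion of Map3k7 had both received tamoxifen for 3 days. Map3k7 encodes TAK1, a kinase that relays Toll-like receptor, TNF receptor and TGF-beta signals to the IKK and MAP kinase cascades. Each group had 3 samples, each hybridised to 1 Affymetrix array. The array medians lay between 3.77 and 3.81 on the log2 scale, and a level near 4 was therefore close to that of the median probe set. The number of arrays limits the precision of every value. Nothing in the labels says that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples.

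Map3k7 itself fell in the sorted cells. Its representative probe set read 6.65 ± 0.06 (SD, 3 arrays) in wild-type cells and 4.05 ± 0.41 (SD, 3 arrays) in knockout cells, a log2 difference of -2.60 with a standard error of 0.19 (limma, Benjamini-Hochberg adjusted p = 0.00128). This is a 6.07-fold lower signal. The second bright probe set fell by 3.25 (SE 0.14, limma adjusted p = 0.000165) and the third by 2.34 (SE 0.32, limma adjusted p = 0.0181). The other 2 of the 5 Map3k7 probe sets were dim in both groups and did not pass, with differences of -0.65 (limma adjusted p = 0.239) and -0.19 (limma adjusted p = 0.65). On each of the 3 bright probe sets every knockout array lay below every wild-type array. Where these probes lie relative to the deleted part of the gene was not analysed here.

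**Figure D1:**
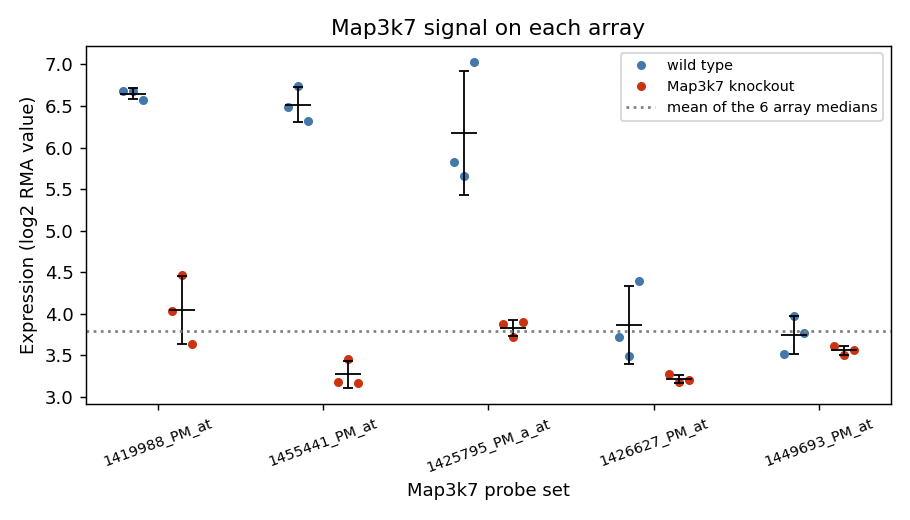
Log2 RMA value (vertical axis) of the 5 Map3k7 probe sets (horizontal axis), 1 point per array, with the mean (horizontal mark) and SD (bar) of the 3 arrays of each group. On the 3 brighter probe sets the knockout arrays lie between 3.17 and 4.46 and the wild-type arrays between 5.66 and 7.03, and the dotted line is the mean of the array medians.

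The comparison asked which transcripts of splenic dendritic cells depend on Map3k7. Knockout cells had more mRNA for Spon1, an extracellular matrix protein, which rose 32.0-fold on its brightest probe set (a log2 difference of 2.20 as the mean of its 4 probe sets, 2 of them past the threshold), and for Slc27a2, a fatty acid transporter and acyl-CoA synthetase, which rose 25-fold. The anti-inflammatory cytokine Il10 rose 7.10-fold, and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 9.26-fold. Transcripts that fell included Relb (2.33-fold lower), Cd40 (1.83-fold lower) and Il12b (1.87-fold lower), which belong to the NF-kB pathway and to dendritic cell activation, and Sqle (3.58-fold lower), an enzyme of cholesterol synthesis. With 1 array left out, Sqle passed in 6 of 6 fits, Relb in 4, Cd40 in 2 and Il12b in 0. With limma and Benjamini-Hochberg adjustment over 45037 probe sets, 184 of 17097 genes were higher and 101 were lower in knockout cells at an adjusted p under 0.05. Of these, 97 and 45 differed at least 2-fold. Counted as probe sets, named or not, 362 were higher and 176 lower.

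The 12 largest increases also took in Lifr, the receptor subunit for leukemia inhibitory factor, which rose by 3.64 on the log2 scale (SE 0.34, limma adjusted p = 0.00404), from 5.49 ± 0.54 to 9.13 ± 0.59 (SD). Pex11a, a protein of peroxisome division, rose by 3.52 (SE 0.26) and the sulfotransferase Sult1a1 by 3.21 (SE 0.16). Sqor, the mitochondrial sulfide oxidase, rose by 2.89, the stress-induced mTORC1 inhibitor Ddit4 by 2.86, the secreted phospholipase Pla2g7 by 2.65, the metallothionein Mt1 by 2.62 and the membrane protein Ms4a6d by 2.58 (limma adjusted p between 0.000269 and 0.0134 for these genes). As the mean of a gene's probe sets the differences were 2.33 for Lifr, 1.48 for Sqor, 1.70 for Mt1 and 1.62 for Ms4a6d, still past the threshold. With 1 array left out Mt1 passed in 5 of 6 fits and Ms4a6d in 4, and the other 10 of these 12 genes in all 6. Spon1 went from 5.03 ± 0.27 to 10.03 ± 0.95 (SD), a difference of 5.0 (SE 0.41, limma adjusted p = 0.0026), and Slc27a2 from 4.41 ± 0.33 to 9.06 ± 0.20, a difference of 4.65 (SE 0.18, limma adjusted p = 0.000158). Il10 was at 4.01 ± 0.10 in wild-type cells, close to the array median, and at 6.84 ± 0.33 in knockout cells.

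Besides Map3k7, the 12 largest decreases took in the globin Hbb-b2, which fell by 3.01 on its brightest probe set (SE 0.48, limma adjusted p = 0.0325) and by 1.09 as the mean of its 3 probe sets, 1 of them past the threshold. The brightest can match several globin transcripts. The serpin Serpinb2 fell by 2.69 (SE 0.44, limma adjusted p = 0.0367). The apolipoprotein L genes Apol7a and Apol7c, close relatives in sequence, fell by 2.69 and 2.40 from levels of 12.16 ± 0.11 and 12.18 ± 0.04 (SD), and the mean of the Apol7a probe sets fell by 1.42. The heat shock gene Hspa1b fell by 2.03 and Procr, the endothelial protein C receptor, by 1.72. Asprv1 fell by 1.88, Ctla2b by 1.87, the long-chain fatty acid receptor Ffar4 by 1.74 and Haus8, a subunit of the augmin complex of the mitotic spindle, by 1.69. These last 8 genes passed with limma adjusted p between 0.00943 and 0.048. With 1 array left out Hspa1b passed in 5 of 6 fits, Asprv1 in 4, Apol7a, Apol7c, Procr and Haus8 in 3, Hbb-b2, Serpinb2 and Ffar4 in 2, and Ctla2b in 1.

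**Figure D2:**
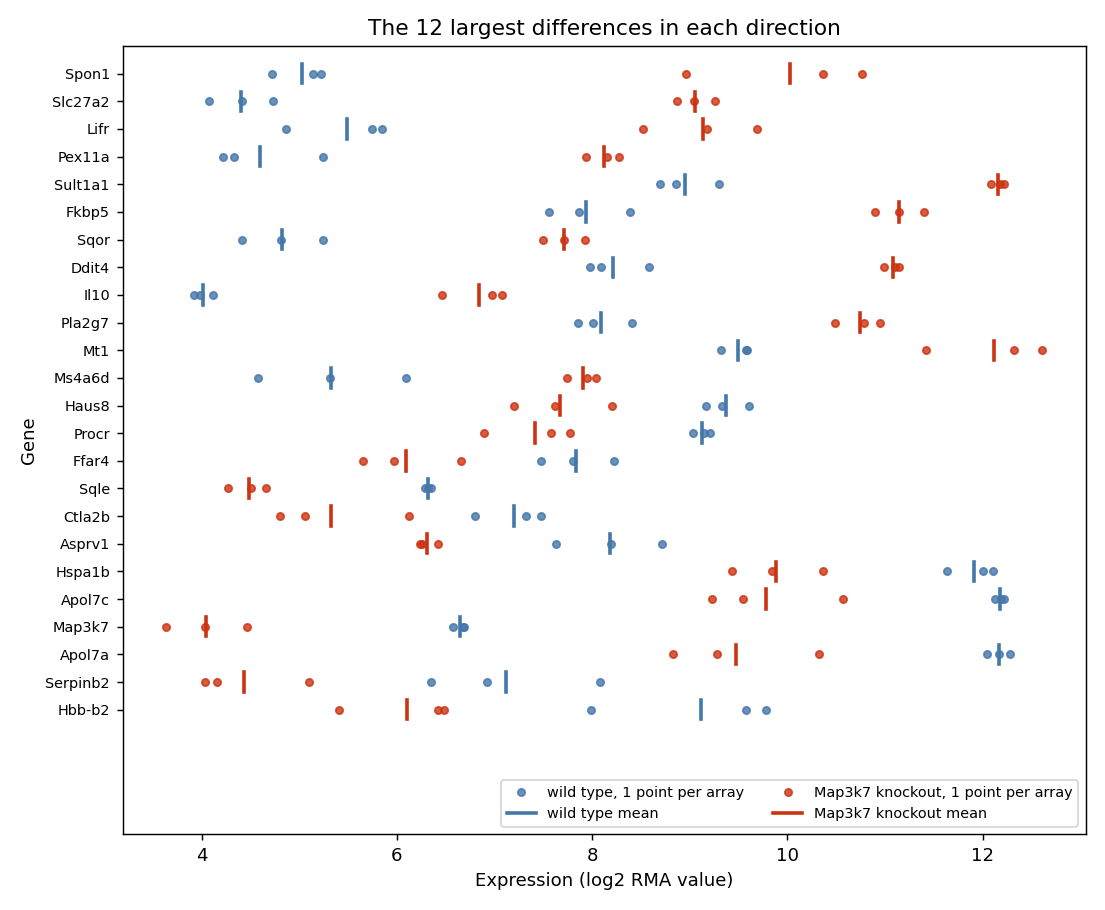
Log2 RMA value (horizontal axis) on each array for the 12 genes with the largest increase and the 12 with the largest decrease past the threshold (vertical axis). Points are single arrays and bars are means of 3 arrays, and the wild-type and knockout points do not overlap for any of these genes, from a difference of 5.0 for Spon1 to -3.01 for Hbb-b2.

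Of 30 NF-kB target genes, 4 fell, 0 rose and 26 did not pass over all probe sets, while 13 were lower adjusted over the list alone. Those that fell were Relb, the partner of p100 in noncanonical NF-kB signalling (-1.22, SE 0.15), the adaptor Traf1 (-0.83, SE 0.11), the costimulatory receptor Cd40 (-0.87, SE 0.14) and Il12b, the p40 subunit of interleukin-12 (-0.90, SE 0.15). The list median was -0.24, and camera, run in limma, called the list lower (Benjamini-Hochberg adjusted p = 1.73e-07, and adjusted p = 0.303 with an estimated correlation, or 0.058 by fry). The list median was -0.10 without genes shared between lists, and Traf1 passed in 3 of 6 fits with 1 array left out. Of 20 costimulation and maturation genes, 3 fell, again Relb, Cd40 and Il12b, and 0 rose, with 10 lower and 1 higher adjusted over the list alone. Their median was -0.46 (camera adjusted p = 2.61e-07, and adjusted p = 0.235 with an estimated correlation).

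Survival genes gave no group call. Of 11 anti-apoptotic genes 0 passed over all probe sets and 1 was lower adjusted over the list alone (median -0.11, -0.13 to 0.01 with 1 array left out, camera adjusted p = 0.504). Cflar, the inhibitor of caspase-8 activation, stood at -0.72 (limma adjusted p = 0.0756). Over 13 alternatives Cflar ran from -0.82 to -0.35 and passed in 1. Xiap, an inhibitor of caspases, stood at 0.22 (limma adjusted p = 0.416). Of 25 pro-apoptotic genes 0 passed, with 4 higher and 1 lower adjusted over the list alone (median 0.02, -0.05 to 0.08 with 1 array left out, camera adjusted p = 0.46). The effector caspase Casp6 stood at 1.04 (limma adjusted p = 0.0974) and cytochrome c, Cycs, at -0.61 (limma adjusted p = 0.0774). Over 13 alternatives Casp6 ran from 0.57 to 1.29 and passed in 2, and Cycs ran from -0.70 to -0.46 and passed in 3. At an unadjusted p under 0.05, 2805 of the 17097 genes differed.

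Among 28 components of the TAK1, IKK and MAP kinase cascades, the Toll-like receptor adaptor Myd88 rose by 1.1 (SE 0.19, limma adjusted p = 0.0436, past the threshold in 1 of 6 fits with 1 array left out) and 0 fell. Counting those adjusted over the list alone, 3 were higher and 1 was lower (median 0.09, camera adjusted p = 0.136). Camera called the list higher without wild-type replicate 3 (adjusted p = 0.0395) or knockout replicate 1 (adjusted p = 0.0382), and its medians with 1 array left out ran from 0.00184 to 0.12. Among 22 immediate-early and AP-1 genes, the transcription factor Klf2 fell by 0.67 (limma adjusted p = 0.0444, past the threshold in 0 of 6 fits with 1 array left out) and 0 rose. In this list 4 were lower and 1 was higher adjusted over the list alone (median -0.01, -0.04 to 0.10 with 1 array left out, mean 0.02, camera direction down, adjusted p = 0.762). Jun, a subunit of AP-1, stood at -0.46 on its brightest probe set (limma adjusted p = 0.0591), but 1 of its 2 probe sets passed as lower.

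Cytokines and chemokines went both ways. Of 29 measured, 3 rose and 4 fell, with 5 higher and 8 lower adjusted over the list alone. The list median was -0.06 (-0.09 to -0.02 with 1 array left out), its mean 0.01 and the direction by camera down (adjusted p = 0.399). Il10 and the chemokine Ccl6 (1.39, SE 0.10) were among those that rose, and Il12b and the interferon-induced chemokines Cxcl9 (-1.54, SE 0.09) and Cxcl10 (-1.31, SE 0.13) among those that fell. Cxcl9 was the 1 of 18 interferon-gamma response genes that fell, and 0 rose, while 2 were lower adjusted over the list alone. That list had a median of -0.18 (camera adjusted p = 0.0162, and adjusted p = 0.56 with an estimated correlation). It was not called without wild-type replicate 2 (median -0.09, adjusted p = 0.101), knockout replicate 1 (-0.22, adjusted p = 0.0509) or knockout replicate 3 (-0.06, adjusted p = 0.158), by fry (adjusted p = 0.107) or without shared genes (-0.11, adjusted p = 0.406), and its median was -0.28 without knockout replicate 2. Cxcl10 was the 1 of 27 type I interferon-stimulated genes that fell, and 0 rose. There 3 were lower and 1 was higher adjusted over the list alone (median -0.11, camera adjusted p = 0.281). Camera called it lower without wild-type replicate 3 (-0.23, adjusted p = 0.00473) or knockout replicate 3 (-0.16, adjusted p = 0.0212), and without wild-type replicate 2 the median was 0.02.

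Of 14 MHC class II presentation genes 0 passed, over all probe sets or adjusted over the list alone (median 0.01, -0.01 to 0.04 with 1 array left out, camera adjusted p = 0.386). Their smallest p-values belonged to the lysosomal protease Lgmn (0.98, limma adjusted p = 0.166) and the ubiquitin ligase Marchf1 (0.42, limma adjusted p = 0.222). Of 13 MHC class I presentation genes 0 passed, over all probe sets or adjusted over the list alone, but 13 of 13 differences were negative. Their median was -0.17 (camera adjusted p = 0.00732, and adjusted p = 0.308 with an estimated correlation).

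All 34 cell cycle genes had a negative difference, with a median of -0.67. Over all probe sets 2 fell, the replicative helicase subunit Mcm2 (-1.51, SE 0.23, limma adjusted p = 0.029, past the threshold in 1 of 6 fits with 1 array left out) and cyclin E2, Ccne2 (-0.89, SE 0.10, limma adjusted p = 0.0106), and 24 were lower adjusted over the list alone. Camera called the list (adjusted p = 3.17e-16, and adjusted p = 0.297 with an estimated correlation, or 0.058 by fry). Ccne2 was dim, at 4.39 ± 0.15 (SD) in wild-type cells. Of 18 cholesterol synthesis genes 6 fell and 0 rose, with 10 lower adjusted over the list alone and a median of -0.49. They were led by squalene epoxidase, Sqle (-1.84, SE 0.12, limma adjusted p = 0.000634), and the isopentenyl diphosphate isomerase Idi1 (-1.68, SE 0.18, limma adjusted p = 0.00712), followed by the sterol carrier Stard4 (-1.11, SE 0.14) and the sterol desaturase Sc5d (-0.60, SE 0.09). Sc5d passed in 0 of 6 fits with 1 array left out and stood at -0.19 as the mean of its probe sets (adjusted p = 0.282). Camera called this list lower (adjusted p = 3.8e-09, and adjusted p = 0.214 with an estimated correlation), with a median of -0.29 on means of probe sets.

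Of 24 phagocytosis and lysosome genes 4 rose, 0 fell and 20 did not pass, and 12 were higher adjusted over the list alone (median 0.28, camera adjusted p = 6.27e-08, and adjusted p = 0.214 with an estimated correlation). The 4 were the mannose receptor Mrc1 (2.31, SE 0.24), the Fc receptors Fcgr4 (2.08, SE 0.18) and Fcgr3 (1.79, SE 0.26), and Mertk, a receptor for apoptotic cells that is also a macrophage marker (1.16, SE 0.14). Of 14 FoxO target genes 2 rose and 1 fell, and 8 were higher and 1 lower adjusted over the list alone (median 0.44, camera adjusted p = 0.000598, and adjusted p = 0.214 with an estimated correlation). Gadd45a rose by 1.21 and Sesn1 by 0.91, while Klf2 fell. Of 17 TGF-beta and SMAD target genes 2 rose, the integrin subunit Itgae (1.79, SE 0.25) and the matrix protein Tgfbi (0.88, SE 0.13), and 0 fell. With p-values adjusted over the list alone, 4 of them were higher and 1 was lower (median 0.14, camera adjusted p = 0.0153, and adjusted p = 0.303 with an estimated correlation, or 0.0589 by fry). The list was not called without wild-type replicate 2 (median 0.14, adjusted p = 0.0909) or knockout replicate 3 (0.23, adjusted p = 0.0508). Its median was 0.25 without wild-type replicate 3, 0.22 without knockout replicate 2 and 0.33 on probe sets above the median level.

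**Figure D3:**
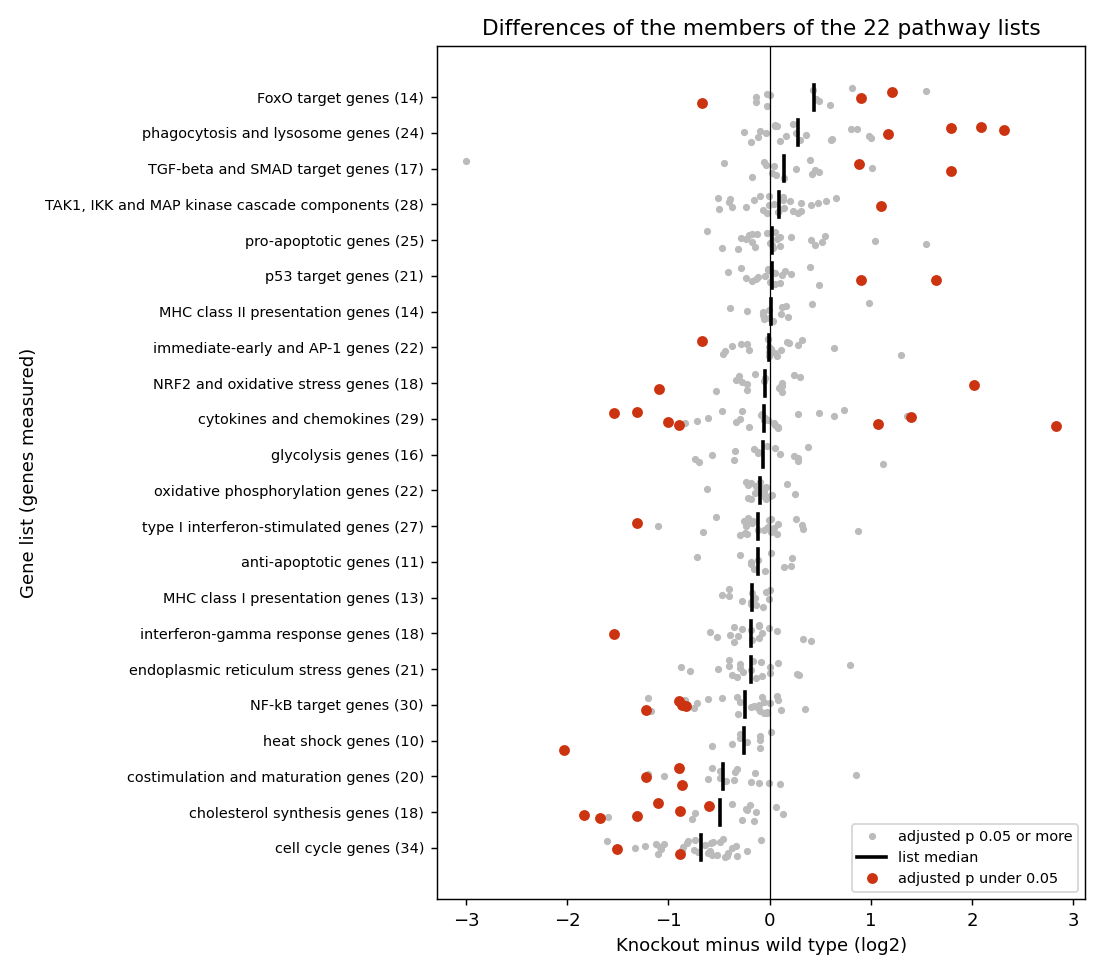
Log2 difference, knockout minus wild type (horizontal axis), of each measured member of the 22 pathway lists (vertical axis, number of genes measured in brackets). Red points are genes with an adjusted p under 0.05, grey points are other genes and the black bar is the list median, which runs from -0.67 for cell cycle genes to 0.44 for FoxO targets.

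Of 10 heat shock genes Hspa1b alone fell, over all probe sets or adjusted over the list alone, and 0 rose (median -0.26, camera adjusted p = 0.0108, and adjusted p = 0.312 with an estimated correlation, or 0.107 by fry). Of 21 endoplasmic reticulum stress genes 0 passed, with 3 lower and 1 higher adjusted over the list alone. Their median was -0.19 (camera adjusted p = 0.0141, and adjusted p = 0.214 with an estimated correlation, or 0.0584 without shared genes). By fry the adjusted p was 0.0018. Without wild-type replicate 3 the medians of these lists were -0.13 and -0.12. Of 21 p53 target genes 2 rose, Trp53inp1 (1.64, SE 0.19, or 0.95 as the mean of its probe sets) and Sesn1, and 0 fell, with 2 higher and 1 lower adjusted over the list alone (median 0.02, camera adjusted p = 0.211, but adjusted p = 0.0444 and up by fry). The p53 median ran from -0.01 to 0.05 with 1 array left out. Among 18 NRF2 and oxidative stress genes, glutathione reductase, Gsr, rose by 2.02 (SE 0.27) and the glutamate-cysteine ligase Gclc fell by 1.09 (SE 0.14). This list had 1 higher and 2 lower genes adjusted over the list alone (median -0.05, -0.07 to -0.03 with 1 array left out, camera adjusted p = 0.411). Of 16 glycolysis genes 0 passed, with 1 higher and 3 lower adjusted over the list alone (median -0.07, -0.12 to -0.00302 with 1 array left out, camera adjusted p = 0.574). Of 22 oxidative phosphorylation genes 0 passed, with 1 lower adjusted over the list alone (median -0.09, camera adjusted p = 0.115). It was called lower without wild-type replicate 3 (-0.15, adjusted p = 0.0181) or knockout replicate 1 (-0.12, adjusted p = 0.0382), and its medians with 1 array left out ran from -0.15 to -0.03.

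Camera with its preset correlation called the marker lists of macrophages and erythroid cells, which neither an estimated correlation (adjusted p = 0.628 for each) nor fry did. Of 18 macrophage markers 4 rose and 0 fell, the scavenger receptor Cd163 (1.58, SE 0.18), Cd5l, a secreted protein with scavenger receptor domains (1.51, SE 0.20), Mertk and transferrin, Trf (0.97, SE 0.15), with 8 higher and 1 lower adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.000881, and adjusted p = 0.628 with an estimated correlation). It was 0.44 without knockout replicate 3 and 0.68 on probe sets above the median level, and Mertk belongs to the phagocytosis list as well. All 9 erythroid markers were negative and 0 passed, with 1 lower adjusted over the list alone (median -0.25, camera adjusted p = 0.00455, and adjusted p = 0.628 with an estimated correlation, or 0.151 with preset correlation on probe sets above the median level). The globin Hba-a1 stood at -3.57 with a standard error of 0.74 (limma adjusted p = 0.0713), beside the fall of Hbb-b2 and the lower cell cycle genes. All 3 Hba-a1 probe sets were lower, and 1 of them passed. Over 13 alternatives Hba-a1 ran from -4.27 to -2.79 and passed in 4. The neutrophil gene S100a8 stood at 2.28 with a standard error of 0.60 (limma adjusted p = 0.147).

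Dendritic cell markers showed no group call. Of 11 markers of conventional dendritic cells Kmo, an enzyme of the kynurenine pathway, rose by 0.66 and 0 fell, with 1 higher and 1 lower adjusted over the list alone (median 0.03, -0.01 to 0.06 with 1 array left out, camera adjusted p = 0.597). The transcription factor Zbtb46 stood at -0.75 (limma adjusted p = 0.0621), but 2 of its 4 probe sets passed as lower, and the mean of the 4 was -0.60 (adjusted p = 0.0336). Of 18 markers of CD8a-positive dendritic cells Itgae and Plekha5 (0.93, or 0.58 as the mean of its probe sets, adjusted p = 0.152) rose and 0 fell, with 2 higher and 4 lower adjusted over the list alone (median -0.03, -0.05 to -0.00118 with 1 array left out, camera adjusted p = 0.601). Of 14 markers of CD4-positive or CD11b-positive dendritic cells, Relb and the ubiquitin ligase Dtx1 (-0.97) fell while Itgam, the CD11b chain, rose by 1.31. In that list 3 were higher and 6 lower adjusted over the list alone (median -0.22, -0.36 to -0.10 with 1 array left out, camera adjusted p = 0.183). Of 18 monocyte markers the lipopolysaccharide co-receptor Cd14 (2.09, SE 0.23) and the transcription factor Cebpb (1.06, SE 0.17) rose and 0 fell, with 5 higher and 3 lower adjusted over the list alone (median 0.12, 0.11 to 0.22 with 1 array left out, camera adjusted p = 0.468).

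No single gene passed over all probe sets in the lists for the remaining cell types. Their medians, with the range over the fits without 1 array in brackets, were 0.08 (0.05 to 0.12) for 17 neutrophil markers, -0.01 (-0.03 to 0.05) for 12 eosinophil, basophil and mast cell markers (mean 0.06, camera direction up), -0.09 (-0.18 to -0.07) for 15 B cell markers and -0.02 (-0.22 to 0.07) for 12 plasmacytoid dendritic cell markers. They were 0.02 (0.02 to 0.05) for 6 plasma cell markers, -0.08 (-0.11 to -0.03) for 12 T cell markers, -0.12 (-0.12 to -0.06) for 12 NK cell markers, 0.04 (-0.03 to 0.09) for 10 platelet markers and -0.09 (-0.13 to -0.05) for 4 sex-linked transcripts. Camera adjusted p-values for these lists lay between 0.128 and 0.605, and without knockout replicate 3 that of neutrophils was 0.0352. Of these markers, 5 of neutrophils and 2 of plasma cells were higher, and 2 of B cells and 1, 1 and 1 of plasmacytoid dendritic cells, plasma cells and platelets were lower, adjusted over the list alone. The sex-linked list pools Xist with transcripts of the Y chromosome, so its median cannot show a difference in sex. Over the 6 arrays Xist lay between 11.43 and 11.77 and the Y-linked Kdm5d between 3.14 and 3.61.

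Leaving out 1 array at a time gave 48 to 247 higher and 13 to 228 lower genes, the fewest without knockout replicate 2 and the most without knockout replicate 1. Camera called 11 of 22 pathway lists with its preset correlation of 0.01 and 0 of 22 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry called 7. These were endoplasmic reticulum stress (fry adjusted p = 0.0018), cholesterol synthesis (0.0115), phagocytosis (0.0115), FoxO targets (0.0246), costimulation (0.0434), MHC class I (0.0487) and p53 targets (0.0444), the last not called by camera. Of the remaining named genes that passed, Ccne2, Cd14, Cd163 and Gadd45a did so in 5 of 6 fits with 1 array left out and Gsr, Itgae and Trp53inp1 in 4. Fcgr3, Gclc, Mertk and Stard4 passed in 3, Cd5l, Cebpb, Dtx1 and Tgfbi in 2, and Itgam, Kmo, Plekha5, Sesn1 and Trf in 1. Quantile normalization ended the calls of Klf2, Ctla2b and Plekha5, the replicate block that of Kmo, trended and robust variances that of Sc5d, and means of probe sets that of Traf1.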

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

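The comparison of control probe sets below was chosen after the data had been seen. The bacterial RNAs added before labelling, outside the comparison of mouse transcripts, gave a higher signal on the knockout arrays, with a mean over 24 probe sets of 5.92 ± 0.22 (SD) against 4.85 ± 0.73 (SD) on the wild-type arrays. The difference was 1.07 on the log2 scale, or 0.66 without wild-type replicate 2, the lowest array, and all 3 knockout arrays lay above all 3 wild-type arrays (2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The bacterial controls added at hybridization differed by 0.08 (exact permutation p = 0.4). Whether the amount added or the RNA input differed between the groups is not known.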

How the results depend on the processing

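The results without shared list genes and without myeloid markers were chosen after seeing the data. Map3k7 stayed lower and past the threshold under every alternative run. Values for the named genes kept their direction in all 1242 comparisons run, with 143 losing and 34 gaining the call. That direction was largely fixed: groups of most named genes did not overlap, so dropping 1 array cannot turn a probe set's difference. Trended variances and the replicate block leave the difference unchanged. Genes not past the threshold had no call to lose. Against 184 higher and 101 lower genes, the mean of a gene's probe sets gave 278 and 181, an adjusted p under 0.01 gave 55 and 14, under 0.10 gave 374 and 272, and a 2-fold minimum gave 97 and 45. Lower genes numbered 171 with trended and robust variances and 159 with array weights. Other changes of probe set or scaling stayed within 1.5 times the counts. Without probe sets ending in x or s, Ctla2a and Tesc turned from -1.19 and -0.72 to 0.12 and 0.07, not past the threshold. Leaving out 1 array gave 48 to 247 higher and 13 to 228 lower genes: 58 and 31 without wild-type replicate 1, 68 and 25 without 2, 114 and 72 without 3, 247 and 228 without knockout replicate 1, 48 and 13 without 2, and 114 and 50 without 3. With fewer arrays the fit has less power, but the cause of these differences was not tested. The replicate block gave 292 higher and 250 lower genes. Same-number arrays deviated from their group means with correlations of 0.05, 0.13 and 0.32, not all over 0.1, and wild-type replicates 1 and 2 did not correlate best with their own number, so the numbers were not taken as paired. Estimated correlation ended all list calls, leaving 0 pathway and 0 cell type lists. Fry, which tests each list on its own, gave 7 and 0. The probe sets above the median level left 1 cell type list, and leaving out 1 array 9 to 14 pathway and 2 to 3 cell type lists. Without shared genes 9 pathway lists were called. Taking myeloid markers out of the finished count left 178 higher genes, which does not test the effect of myeloid RNA on the others. Lists that changed direction were not past the threshold, and the cause was not tested. With the probe sets above the median level the NK cell list had a median of -0.11 and the platelet list -0.0115, with the test turned. Without shared genes the medians were 0.0806 for anti-apoptotic, 0.0161 for immediate-early and 0.0147 for cytokine genes. Leaving out 1 array gave medians of -0.0393 to 0.10 for immediate-early genes, -0.0892 to -0.0238 for cytokines, -0.22 to 0.0652 for plasmacytoid dendritic cell markers and -0.0271 to 0.0877 for platelet markers. Signals near the array median limit what can be said of dim genes.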

Other observations

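Camera and fry on the p53 target list were planned, and the further glucocorticoid-induced genes were listed before their values were seen. The fit without wild-type replicate 2 was planned too, but its use here was chosen afterwards. All other tests in this part were chosen after the result they bear on had been seen. The genes this part names were picked in the same way unless the report names them. Beside Fkbp5, Ddit4, Mt1, Sult1a1 and Il10, knockout cells had higher levels of other genes that glucocorticoids induce: Socs3, an inhibitor of cytokine signalling, rose by 2.34 on the log2 scale (SE 0.30, limma adjusted p = 0.0134), and the transcription factors Klf9 and Zbtb16 rose by 1.89 (SE 0.21, limma adjusted p = 0.00867) and 1.88 (SE 0.26, limma adjusted p = 0.0173). Of 18 such genes put together after their values had been seen, 13 were higher and 0 lower, with a median of 1.76, and this count is therefore no evidence for the group. The first principal component held 47.5% of the variance, and on it all 3 wild-type arrays lay on one side of all 3 knockout arrays. The second held 21.98% and did not separate the groups. On it wild-type replicate 3 (-38.61) and knockout replicate 3 (-17.57) lay apart from the other arrays, which ran from 2.16 to 23.15. Whether the arrays numbered 3 shared a factor besides their group is not known.

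One hypothesis is that knockout mice had a higher glucocorticoid level, which raised these genes. It was tested on further glucocorticoid-induced genes, listed before their values were seen: the median of the 24 measured was 0.10, at percentile 99.55 of 10000 random lists matched on mean expression. The support is modest, since only Cebpd passed (0.91, limma adjusted p = 0.0112), 15 of 24 were positive, and camera gave p = 0.031, or 0.075 with an estimated correlation. Some of the 24 lay below the array medians in wild-type and knockout cells, such as Pdk4 (3.03 and 3.08) and Cdkn1c (3.29 and 3.22). There a rise may hardly show. Brighter ones that did not pass went both ways, among them Tsc22d3 (0.90), Per1 (0.66), Rhob (-0.50) and Anxa1 (-0.48). More macrophage RNA as the whole cause stays open. The 14 glucocorticoid-induced genes past the threshold had a median above that of Cd5l, C1qa, C1qb, C1qc and Fcna by 1.39 (SE 0.38 from resampling genes, not arrays). But these 14 were kept for their rise, and Cd163 and Mertk among them are themselves macrophage markers. The 24 further genes lay below the 5 by 0.61 (SE 0.21, also from resampling genes). Dendritic cells that express the 5 would damp the rise of the 5, and dim genes among the 24 would lower their median. Hormone was not measured here, and other signals that may induce the same genes stay open, as does an effect of Map3k7 loss within the cells.

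The higher macrophage markers may reflect more macrophage RNA in the sorted cells, since splenic macrophages can carry CD11c through the sort, or a change in the dendritic cells themselves. Of 11 markers with a mean of at least 6, 6 had a 95% interval above 0, among them C1qa at 0.70 and C1qb at 0.84. The intervals of Spic (0.0047), Slc40a1 (0.22) and Adgre1 (-0.28) included 0. The other 2 markers had one below 0, Hmox1 at -0.53 and Hpgd at -1.12. Added macrophages alone would not lower those 2, but a fall of both in the dendritic cells would hide a rise, so the explanations cannot be told apart.

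Lower cell cycle genes could come from fewer cycling erythroid precursors, since globins were lower too, although the sort for CD11c should remove most of them. The 8 erythroid markers other than globins had a median of 3.82 in wild-type cells, near the array median, where probe sets may hardly respond, so this stays open. The wild-type array with the lowest added controls does not set the difference alone: without wild-type replicate 2 the list median was -0.58, against -0.67 with all arrays, and 33 of 34 genes stayed negative. A p53 response stays open. The median of 6 canonical targets was 0.0791 (SE 0.0846 from resampling genes) with 4 positive and 2 negative, which decides nothing. Fry called the p53 target list up (adjusted p = 0.0444) and camera did not. Fewer cycling cells of other kinds and slower cycling after Map3k7 loss were not tested.

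The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, gave 285 genes past the threshold, and the highest of the others gave 0. Each of the others mixes wild-type and knockout arrays, so the difference between the groups adds to its spread. Its count therefore does not show what arrays without a difference would give. For pathway lists called by camera the real split, again 1 of 10, gave 11, and the highest of the others gave 9, that of wild-type replicates 1 and 2 with knockout replicate 1 against the rest.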
